A study of Mus musculus with 11 samples.

How the data were processed

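Input libraries of 3 constructs were analysed, 2 each of empty vector, METTL1 wild type with WDR4, and METTL1 labelled mutant with WDR4, in mouse embryonic fibroblasts with SV40 T antigen. Per the labels' protocols, small RNA was treated with wild-type and mutant AlkB to remove other methylations, and input libraries were made from it without the cleavage step, with a small RNA kit for Illumina sequencing. The protocols describe only the empty vector and the wild-type construct, and the labels do not say which change the mutant carries. Nothing from the 5 cleaved libraries was used here.

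Per the submitters' processing notes, Trim Galore, Bowtie, bedtools and the mouse build mm10 were used, with no versions given. How reads that fit several tRNA genes were treated is not given in the sources used here. The authors deposited 2 tables, 1 for each METTL1 construct, with the same 301 tRNA entries and the same empty vector columns in both. The authors gave abundance as RPM, reads per 1000000 reads over tRNA entries, in each library. The authors also gave a fold change, the ratio of mean RPM with METTL1 to mean RPM with empty vector, and its log2 value. The authors' deposited p-value is not adjusted and equals a two-sided test on untransformed RPM that assumes equal variances, and the −log10 of that p-value is given beside it per the file headers. All values used for tests here come from the RPM columns. Entries are named without the prefix they carry in the tables.

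Every RPM value is a whole multiple of the value of 1 read, within a tolerance of 0.01 reads, so the implied total of each library could be read from the table. The totals ranged from 5405585 to 16003708 reads, and 364 to 1379 reads per library were not in the table. If reads were counted in several entries, these totals would exceed the reads sequenced, and the chi-square values below would be too high. No test for a change in abundance was run on the implied reads, which served only for measures of counting error. Between replicates the chi-square per degree of freedom of these reads was 116 for empty vector, 85.1 for wild type and 706 for the mutant, so replicates differed far beyond counting error.

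RPM was transformed to log2(RPM + 1) with a pseudocount of 1, and no entry was left out for low values. Each comparison was fitted in limma 3.58.1 under R 4.3.3 on its own 4 libraries, without covariates, with the prior variance following a trend in the mean. P-values were adjusted with the Benjamini-Hochberg (BH) method over the 301 entries, and an adjusted p under 0.05 was called. Log2 fold changes are given with limma's standard error. The design fixed before the data were examined had all 6 input libraries in a common fit only if a common table of counts held them. As the values are RPM in 2 tables, each comparison used its own libraries. The common fit had been run as well, and the calls of both fits had been seen when this choice was settled, so both are reported: 69 higher and 2 lower for wild type in the common fit against 91 and 22. The comparison of wild type with mutant takes columns from both tables, whose empty vector columns are identical. The trend and the absence of a filter were chosen after the data were seen. The design had foreseen count tests and a camera set test if the unit were counts, and neither was run.

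The lists were fixed before the data were examined, from background knowledge of tRNA variable loops. The m7G list held 20 anticodon families with 176 entries (Ala-AGC, Ala-CGC, Ala-TGC, Arg-TCT, Asn-GTT, Cys-GCA, Ile-AAT, Ile-TAT, Lys, Met, Phe, Pro-AGG, Pro-CGG, Pro-TGG, Trp, Tyr and Val families). Initiator and elongator methionine tRNA are not told apart by the entry names. The no-m7G list held 26 families with 105 entries (Asp, Glu, Gln, Gly, His, Leu, Ser and SeC families and Arg-ACG, Arg-CCG, Arg-CCT and Arg-TCG), with the Leu, Ser and SeC families also taken alone. The other 20 entries were in neither list, and SupTTA1 among them formed the other RNA list. Family means were compared between the m7G and no-m7G lists with a two-sided permutation test of the difference of medians, 100000 resamples.

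Entries were named by a rule fixed before the data were examined. It takes all Arg-TCT entries and, in each arm, the 10 largest rises and 10 largest falls past the threshold, with at most 2 per anticodon family. Where fewer than 5 passed in a direction, the entries with the smallest p in that direction were added up to 5, as values. For wild type against mutant it takes the 5 largest differences in each direction, 1 per family, and it adds the families of the m7G list in which most entries passed. AspGTC, GluTTC and HisGTG as families, and other entries named in the closing section where said, were chosen after their values were seen.

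Near-identical entries were sought among 243 entries with a mean of at least 10 RPM: 46 pairs lay within 1% of each other in all 6 libraries, and 34 groups within 5% held 88 entries. Both tolerances were picked after a range of values had been tried. Shared controls were weighed by simulating unchanged groups from the spread of each group. The limma fit was tested on simulated data with 60 of 301 entries changed, in 20 rounds. It recovered 71.5% of 1.5-fold and 83.7% of 2-fold changes for wild type against empty vector, 56.3% and 75.2% for mutant against empty vector, and 59.3% and 81.7% for wild type against mutant. Of its calls 6.05%, 5.85% and 6.42% were false in the 3 comparisons, slightly above the nominal 5%. The list test, in 100 simulated rounds, called 3% of rounds without a difference and 100% with 0.3 added to the m7G families. Only an addition of 0.3 was simulated, so the power for smaller differences is not known. The other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

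Alternatives fixed before the data were examined were centring on the no-m7G list, minimum mean RPM of 10 and 100, thresholds of 0.01 and 0.1, minimum changes of 1.5-fold and 2-fold (0.585 and 1 on the log2 scale), 1 value per entry name without its number, the replicate number as a block, leaving out each library, and other summaries, units and lists for the family test. Alternatives chosen after seeing the data were centring on all entries, pseudocounts of 0.1 and 10, no trend in the prior variance, 1 entry per near-identical group, RPM summed per anticodon, all 3 groups in 1 fit, the authors' p-values with BH adjustment, and the family test without each library or without groups that span both lists, the correlation of the arms with 1 empty vector library to each, and shares by amino acid with each near-identical group weighted as 1 entry.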

Results

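TRAC-seq, an assay that finds N7-methylguanosine (m7G) in tRNA by chemical cleavage at the methylated base, was run on mouse embryonic fibroblasts that carry SV40 T antigen. The cells had been transduced with empty vector, with wild-type METTL1 and WDR4, or with a METTL1 labelled mutant and WDR4. METTL1 is the methyltransferase, and WDR4 its partner, of the complex that places m7G in the variable loop of a subset of tRNAs. The series holds 11 libraries. Of these, 6 are input libraries of AlkB-treated, uncleaved small RNA, 2 for each construct, and they measure relative tRNA abundance. The other 5 are cleaved libraries, 1 of them from empty vector cells, and m7G cleavage is not analysed here.

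Abundance was given for 301 tRNA entries in RPM (reads per 1000000 reads over tRNA entries), each entry named by amino acid, anticodon and a number. RPM has almost the same sum in each library, so rises and falls are changes in the share of tRNA reads. A change in the total amount of tRNA cannot be seen in these values. No coordinates of the entries were used here. The values imply totals of 16003708 and 5405585 reads in the empty vector libraries 1 and 2, 10519149 and 13814411 in the wild-type METTL1 libraries, and 13634835 and 10032452 in the mutant METTL1 libraries. These totals would overstate depth if reads were counted in several entries. A value of 0 occurred for 5 entries, all in empty vector library 2, where 3 reads, the limit that a count of 0 allows, are worth 0.555 RPM. This limit covers counting error only. Between the 2 libraries of a group the median SD per entry on the log2 scale was 0.08 for empty vector, 0.06 for wild-type METTL1 and 0.15 for mutant METTL1. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. An exact permutation test of 2 against 2 libraries cannot give a p below 0.33, so entries were tested with limma, which shares the spread across entries.

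The first comparison asked which tRNAs changed in abundance in cells with wild-type METTL1 and WDR4 relative to empty vector. The methionine entry MetCAT22 rose most, from 166 ± 30.1 to 789 ± 30.4 RPM (SD, n = 2 libraries each; log2 fold change 2.25, SE 0.11, limma BH-adjusted p = 1.8e-12). ArgTCT81, whose anticodon reads the arginine codon AGA, rose from 19.5 ± 6.18 to 56.1 ± 3.90 RPM (log2 fold change 1.51, SE 0.16, limma BH-adjusted p = 4.6e-07). The aspartate entry AspGTC21 rose from 258 ± 3.03 to 542 ± 21.6 RPM (log2 fold change 1.07, SE 0.10, limma BH-adjusted p = 8.5e-08), and the glutamate entry GluTTC28 from 1181 ± 52.0 to 2226 ± 81.2 RPM (log2 fold change 0.91, SE 0.09, limma BH-adjusted p = 1.5e-07). The other large rises were those of AlaAGC183 (log2 fold change 1.05, at 1.09 RPM in empty vector), MetCAT13 (0.99), CysGCA70 (0.95), SerGCT8489 (0.94), CysGCA129 (0.92) and SeCTCA2 (0.85), the tRNA that inserts selenocysteine. All of these 10 entries passed the threshold in each alternative limma fit that kept them.

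The m7G list holds the anticodon families that background knowledge gives as carrying the methylated G. Its families with most entries past the threshold were the following, while families outside it reached like shares. In CysGCA 20 of 28 entries rose and none fell (mean log2 fold change 0.47), in LysCTT 18 of 22 (0.50) and in LysTTT 4 of 5 (0.47). In ProAGG 3 of 4 entries rose (0.51), in ProTGG 4 of 6 (0.38) and in ProCGG 1 of 1 (0.36). These 6 families kept a positive mean when libraries were centred on the no-m7G list or on all entries, with 16 and 13 CysGCA and 12 and 11 LysCTT entries then past the threshold. The abundant alanine families AlaCGC and AlaTGC had 5 of 8 and 6 of 10 entries lower and 1 higher in each. Their medians were −0.15 and −0.15, while the means were −0.01 and 0.02, so in AlaTGC mean and median differ in sign, and under the centrings the AlaTGC mean was −0.07 and −0.12 with no entry higher. The largest group of near-identical entries, 7 that may not be separate measurements, lies in these families. Outside the m7G list, 4 of 4 AspGTC entries rose (mean 0.63), as did 2 of 2 GlyTCC and 2 of 3 GluTTC entries. These counts were the same under both centrings.

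The falls were smaller. The largest were those of the suppressor-type entry SupTTA1 (log2 fold change −0.55, at 4.13 RPM in empty vector), ValCAC18 (−0.40), ValCAC37 (−0.34) and ArgCCG2 (−0.31). LeuTAG7 (−0.27), LeuTAG10 (−0.26), LeuAAG3 (−0.24), AlaAGC177 and AlaAGC588 (−0.23 each, near-identical values) and LeuAAG2 (−0.23) followed. Each of these 10 falls lost its call without wild-type METTL1 library 1, and all except ValCAC18 and ArgCCG2 without library 2.

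Of the 6 Arg-TCT entries, the family the study follows, ArgTCT81 alone rose. The log2 fold changes of the other 5, from ArgTCT31 with 0.02 to ArgTCT51 with 0.33, did not pass (limma BH-adjusted p 0.072 to 0.896), although ArgTCT126 did without empty vector library 2 (0.30, limma BH-adjusted p = 0.0058). ArgTCT65, the most abundant, stood at 1843 ± 167 RPM in empty vector and 1911 ± 18.8 RPM with wild-type METTL1 (SD, n = 2).

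In all, 91 of 301 entries rose, 22 fell and 188 were not called at a limma BH-adjusted p under 0.05, and 135 had an unadjusted p under 0.05. In the m7G list of 176 entries 65 rose and 15 fell, or 67 and 16 adjusted over the list alone. In the no-m7G list of 105 entries 25 rose and 6 fell (21 and 5 adjusted over the list alone). Its part with a long variable arm, the 43 Leu, Ser and SeC entries, had 7 higher and 5 lower (7 and 5 adjusted over the list alone). Of the 20 entries in neither list 1 rose and 1 fell (1 and 0 adjusted over the list alone), and the entry that fell, SupTTA1, is also the only entry of the other RNA list (0 and 1 adjusted over the list alone). The median log2 fold change of all entries was 0.16. Centring on the no-m7G list shifted it by −0.09 and gave 61 higher and 26 lower, and centring on all entries shifted it by −0.14 and gave 56 higher and 42 lower. The count of higher entries was 58 without wild-type METTL1 library 1 and 50 without library 2, and that of lower entries 0 and 2, 9 without empty vector library 2, and 2 when all 3 groups were fitted together.

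**Figure D1:**
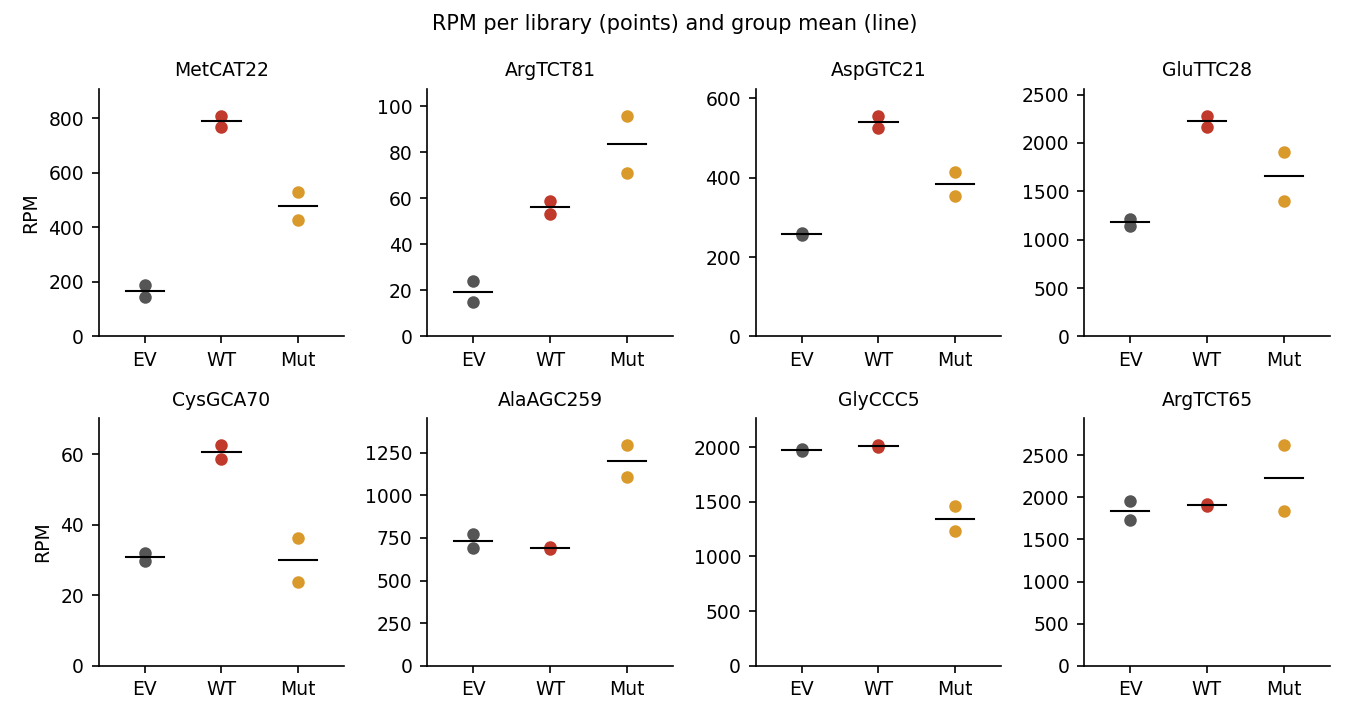
RPM of 8 tRNA entries in each input library, with EV for empty vector, WT for wild-type METTL1 with WDR4 and Mut for the METTL1 labelled mutant with WDR4. Points are libraries and lines are group means. MetCAT22 and ArgTCT81 lie above empty vector in all 4 METTL1 libraries, and CysGCA70 in the WT libraries (60.8 RPM) but not the Mut mean (30.0 RPM).

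**Figure D2:**
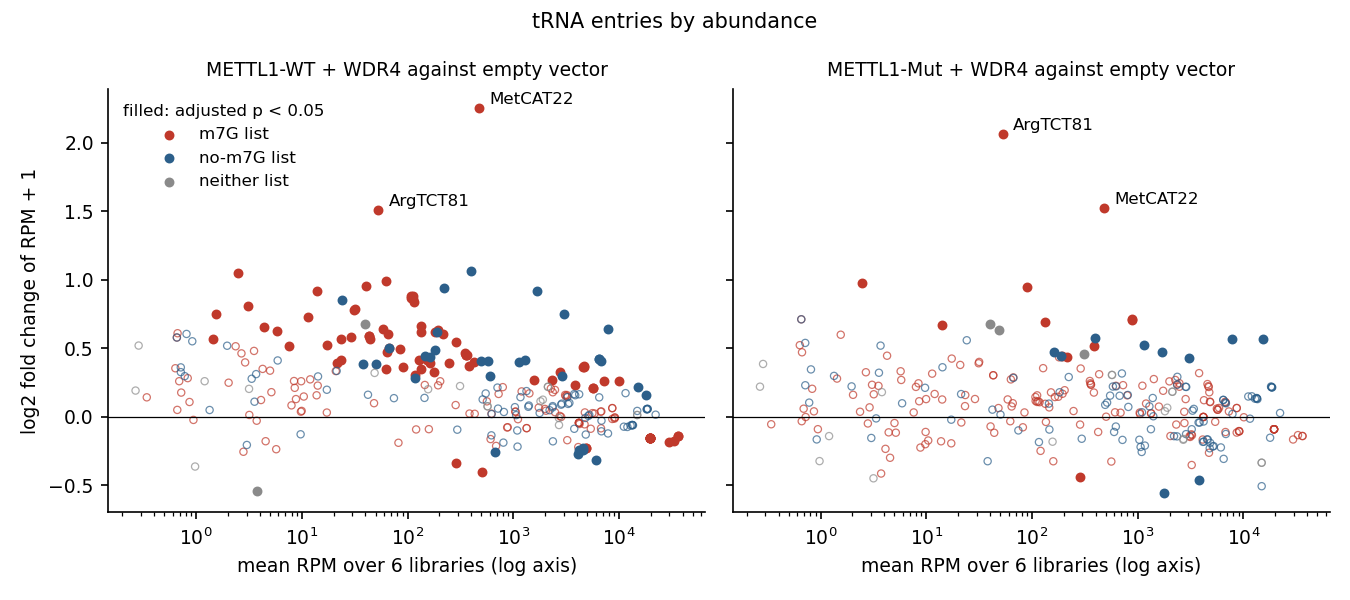
Log2 fold change of each entry against empty vector (vertical axis) by its mean RPM over the 6 input libraries (horizontal log axis), for wild-type METTL1 on the left and the METTL1 labelled mutant on the right. Filled points passed a limma BH-adjusted p under 0.05. With wild-type METTL1, 27 of the 41 entries at 10 to 100 RPM rose, against 3 of the 31 entries at 10000 RPM or more.

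The second comparison asked the same of the METTL1 labelled mutant. ArgTCT81 rose most, from 19.5 ± 6.18 to 83.6 ± 17.5 RPM (SD, n = 2 libraries each; log2 fold change 2.06, SE 0.18, limma BH-adjusted p = 4.2e-25), and MetCAT22 from 166 ± 30.1 to 478 ± 71.8 RPM (log2 fold change 1.52, SE 0.14, limma BH-adjusted p = 8.6e-22). AlaAGC410 rose from 64.2 ± 5.30 to 124 ± 6.30 RPM (log2 fold change 0.94, SE 0.16, limma BH-adjusted p = 1.1e-06). These 3 calls held in each alternative limma fit that kept the entry. The very small p-values rest on a spread pooled over entries, which may not be independent.

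Other rises were those of AlaAGC183 (0.97), ProAGG13 (0.69), the threonine entries ThrAGT131 (0.68) and ThrAGT44 (0.63), CysGCA129 (0.67), AspGTC21 (0.57) and AspGTC42 (0.57), each lost without at least 1 empty vector library. All 4 AspGTC entries rose (mean 0.53), but 0 of 4 passed when libraries were centred on the no-m7G list (mean 0.48). When libraries were centred on all entries 3 of 4 passed (mean 0.44). Of the families that rose with wild-type METTL1, CysGCA had 1 of 28 entries higher (mean 0.12), LysCTT 2 of 22 (0.20), LysTTT 0 of 5 (0.16), ProAGG 1 of 4 (0.48), ProTGG 0 of 6 (0.19) and ProCGG 0 of 1 (0.22). Calls were harder to reach in this arm. The median SD was 0.15 between mutant and 0.06 between wild-type libraries, and 56.3% against 71.5% of simulated 1.5-fold changes were recovered. ProAGG, with 3 of 4 entries higher at a mean of 0.51 for wild type, shows that like means can give unlike counts. Under both centrings 0 CysGCA and 0 LysCTT entries were higher, while ProAGG kept 1. GlyCCC5 (−0.56), SerTGA15 (−0.46) and ValCAC37 (−0.44) fell, and each of these calls was lost without either empty vector library. Among entries that did not pass, the smallest p-values on the lower side belonged to HisGTG6 (−0.51, limma BH-adjusted p = 0.057) and AsnGTT569 (−0.35, limma BH-adjusted p = 0.15). HisGTG6 passed in 7 of 14 alternative fits, among them those at a minimum of 10 or 100 RPM, and AsnGTT569 in 2 of 14.

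In Arg-TCT, ArgTCT31 rose besides ArgTCT81, from 334 ± 48.4 to 485 ± 133 RPM (SD, n = 2; log2 fold change 0.52, SE 0.14, limma BH-adjusted p = 0.0071), a call lost without empty vector library 1, without mutant library 1 (0.23), under centring on the no-m7G list and without the variance trend. ArgTCT51 (0.38), ArgTCT65 (0.26), ArgTCT57 (0.23) and ArgTCT126 (0.09) did not pass (limma BH-adjusted p 0.33 to 0.76), although ArgTCT65 did without mutant library 2 (0.51, limma BH-adjusted p = 0.032).

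In all, 22 entries rose, 3 fell and 276 were not called, with 48 at an unadjusted p under 0.05. Given the wider spread between mutant libraries, these counts cannot be set directly against those for wild type. The m7G list had 11 higher and 1 lower (9 and 1 adjusted over the list alone), the no-m7G list 8 and 2 (9 and 3 adjusted over the list alone), the Leu, Ser and SeC entries 0 and 1 (0 and 0 adjusted over the list alone), with 4 at an unadjusted limma p under 0.05, the entries in neither list 3 and 0 (3 and 0 adjusted over the list alone), and the other RNA list 0 and 0 (0 and 0 adjusted over the list alone), with SupTTA1 at 0.18. The median log2 fold change of all entries was 0.09. Centring on the no-m7G list shifted it by −0.05 and gave 6 higher and 2 lower, and centring on all entries shifted it by −0.10 and gave 13 higher and 6 lower. The larger shift thus kept more rises. Under centring on the no-m7G list ArgTCT81 stayed at 2.01, against 2.06, while its limma BH-adjusted p went from 4.2e-25 to 0.0010. The spread used by the fit therefore changed as well, and the shift alone does not account for the lost calls. Without empty vector library 1 or 2 the counts were 6 higher and 0 lower each, and the fit with replicate number as a block gave 12 and 1.

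The third comparison tested wild-type against mutant METTL1 directly. CysGCA70 was higher with wild-type METTL1, at 60.8 ± 2.84 against 30.0 ± 8.91 RPM (SD, n = 2 libraries each; log2 difference 1.03, SE 0.18, limma BH-adjusted p = 2.4e-06), as was MetCAT22 (log2 difference 0.73, SE 0.13, limma BH-adjusted p = 1.7e-06). AlaAGC259 was lower, at 692 ± 10.3 against 1203 ± 133 RPM and 732 ± 59.7 RPM in empty vector (log2 difference −0.79, SE 0.12, limma BH-adjusted p = 4.2e-08), and ArgTCT81 was lower (log2 difference −0.55, SE 0.17, limma BH-adjusted p = 0.015). The CysGCA70 call was lost without wild-type library 2 (limma BH-adjusted p = 0.066). The ArgTCT81 call was lost with replicate number as a block (limma BH-adjusted p = 0.065), without mutant library 1 (−0.34, limma BH-adjusted p = 0.068) and without either wild-type library. Of the families above, 6 of 28 CysGCA entries (mean 0.35), 4 of 22 LysCTT (0.29), 2 of 5 LysTTT (0.31) and 1 of 6 ProTGG (0.19) were higher, and 0 of 4 ProAGG (0.03) and 0 of 1 ProCGG (0.14). The ProAGG mean turned to −0.07 and −0.08 under the 2 centrings, and the other families kept their sign. Under both centrings 2 LysCTT and 0 LysTTT entries were higher, with CysGCA and ProTGG unchanged at 6 and 1. The histidine family HisGTG had 2 of 3 entries higher (mean 0.46), and neither call held under either centring.

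In all, 34 entries were higher, 11 lower and 256 not called, with 78 at an unadjusted p under 0.05. The m7G list had 18 higher and 7 lower (17 and 6 adjusted over the list alone), the no-m7G list 15 and 3 (15 and 3 adjusted over the list alone), the Leu, Ser and SeC entries 3 and 2 (3 and 2 adjusted over the list alone), the entries in neither list 1 and 1 (1 and 1 adjusted over the list alone), and the other RNA list 0 and 1 (0 and 1 adjusted over the list alone). Of the 91 entries that rose with wild-type METTL1, 26 were higher with wild-type than with mutant METTL1, 2 were lower and 63 showed no call. The median difference over all entries was 0.10. Centring on the no-m7G list shifted it by −0.11 and gave 17 higher and 16 lower, and centring on all entries shifted it by −0.11 and gave 16 and 17. Without wild-type library 1 or 2 the counts were 2 and 2, or 1 and 2, and without mutant library 1 or 2 they were 79 and 37, or 87 and 43. The block fit gave 20 and 5.

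The m7G list was then set against the no-m7G list with 1 mean value per anticodon family, 20 families against 26, since entries of a family may share reads. With wild-type METTL1 the median family log2 fold change was 0.15 in the m7G list and 0.15 in the no-m7G list (difference 0.00083, two-sided permutation p = 0.991). With mutant METTL1 the medians were 0.04 and 0.04 (difference 0.0025, two-sided permutation p = 0.945), and for the difference between the constructs 0.07 and 0.09 (difference −0.0189, two-sided permutation p = 0.726). The BH-adjusted permutation p was 0.991 for each of the 3 tests. As the power of this test was simulated only for a difference of 0.3, smaller differences between the lists are not excluded. With the entry in place of the family as the unit, the wild-type difference was 0.0913 (two-sided permutation p = 0.0387), a unit that treats near-identical entries as independent. Families of both lists spread widely around like medians, from cysteine, lysine and proline families in the m7G list to AspGTC and GluTTC (mean 0.58) in the no-m7G list.

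**Figure D3:**
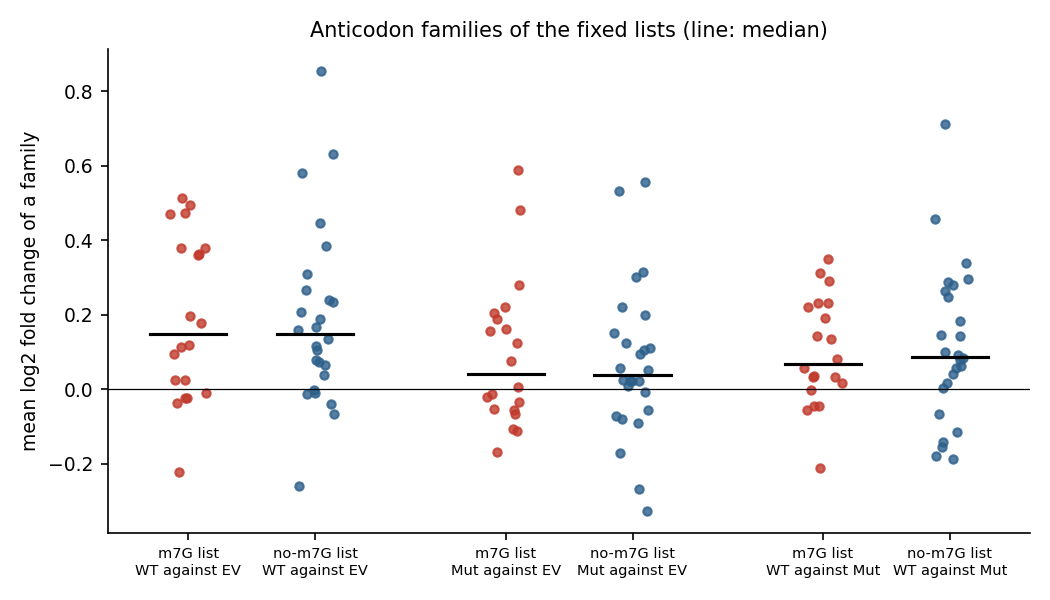
Mean log2 fold change of each anticodon family (points) in the m7G list (20 families) and the no-m7G list (26 families), for each of the 3 comparisons, with EV for empty vector. Lines are medians, which differ between the lists by 0.00083, 0.0025 and −0.0189.

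Both arms were compared with the same empty vector libraries. Across the 301 entries their log2 fold changes had a Pearson correlation of 0.591 and a Spearman correlation of 0.506, where entries are not independent replicates. Simulated unchanged groups that shared those controls gave a mean correlation of 0.518 and a highest of 0.694 in 1000 simulations. The covariance was 0.0551 against 0.0133 simulated, a difference of 0.0417. The sign was the same for 70.8% of entries (65.6% simulated). MetCAT22, ArgTCT81 and the 4 AspGTC entries were among 17 entries higher in both arms, where independent lists would share 6.65, and 1 entry, ValCAC37, was lower in both (0.219 for independent lists). Simulated unchanged groups made almost no calls (means of 0.04 and 0 in 100 simulations), so they set no value for the shared calls. Part of the excess may come from the shared controls. A split chosen after seeing the data gave each arm a single empty vector library. The correlation was then 0.397 or 0.390, depending on which library went to which arm, and the covariance 0.0424 or 0.0412. MetCAT22 and ArgTCT81 were among 3 entries higher in both arms either way (1.81 and 2.31 for independent lists).

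**Figure D4:**
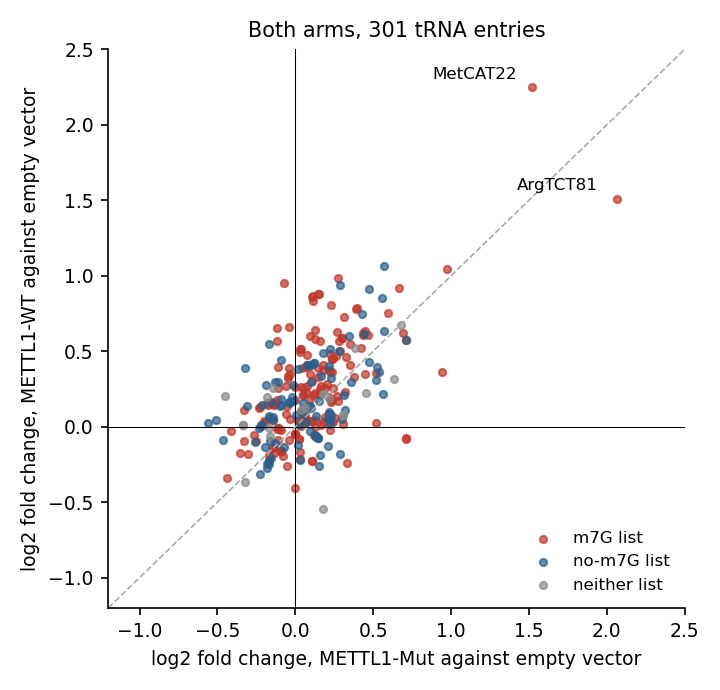
Log2 fold change against empty vector with wild-type METTL1 (vertical axis) and with the METTL1 labelled mutant (horizontal axis) for 301 tRNA entries, coloured by list. The dashed line marks equal values. MetCAT22 (2.25 and 1.52) and ArgTCT81 (1.51 and 2.06) lie apart from the other entries, which reach at most 1.07 and 0.97.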

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

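The tests of explanations in this part were chosen after the results were seen.

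Wild-type and mutant METTL1 differed from each other for 34 entries that were higher and 11 that were lower with the wild type, by a limma test of the difference itself. The largest in the higher direction were CysGCA70 (log2 difference 1.03), LysCTT117 (0.77), MetCAT22 (0.73), GlnTTG12 (0.72) and HisATG3 (0.71). On the lower side stood AlaAGC259 (−0.79), SupTTA1 (−0.73), ValCAC7 (−0.57), ArgTCT81 (−0.55) and ArgTCG2 (−0.47). MetCAT22 and AlaAGC259 held in each alternative limma fit that kept them. CysGCA70 was lost without wild-type library 2, and LysCTT117, GlnTTG12, HisATG3, SupTTA1, ValCAC7, ArgTCT81 and ArgTCG2 without either wild-type library. With replicate number as a block GlnTTG12, SupTTA1, ValCAC7 and ArgTCT81 were lost too, and so were GlnTTG12 under both centrings and with a pseudocount of 10, ValCAC7 with a pseudocount of 0.1, and ArgTCT81 without mutant library 1 (−0.34). GlnTTG12 (1.5 against 0.52 RPM), LysCTT117 (6.29 against 3.26), SupTTA1 (2.50 against 4.78) and ValCAC7 (4.50 against 7.17) rest on few RPM, where each group mean comes from 2 libraries.

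MetCAT22 and ArgTCT81 rose in both arms. MetCAT22 was higher with wild type than with the mutant, while the lower value of ArgTCT81 with wild type lost its call in 4 of the alternative fits named above. A chance low value in 1 of the shared empty vector libraries is argued against, since with either left out the largest limma BH-adjusted p over both entries and both arms was 1.5e-07. Reads shared in a fixed proportion with other entries of the same anticodon are argued against too. Each entry exceeded the highest other member of its family with at least 10 RPM by 1.18 or more on the log2 scale (SE 0.22 for the smallest gap). The gap cannot decide on a proportion that differed between groups. ArgTCT81 stood at 19.5, 56.1 and 83.6 RPM with empty vector, wild type and mutant, where the abundant ArgTCT65 stood at 1843, 1911 and 2232 RPM. A feature common to both METTL1 lines, such as WDR4, the introduced METTL1 whatever its activity, or the lines themselves, may account for the shared part. The lowest log2 fold change over both entries and arms was 1.51, and since these features coincide with the constructs, METTL1 activity and the line cannot be told apart.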

How the results depend on the processing

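The counts of entries depended on the setting. The named entries were mostly picked as the largest changes, so their stability cannot be compared with that of the counts. No entry called in a comparison changed sign in any refit. Over the named entries 598 alternative values gave the same call, 117 kept the direction without passing, 12 passed where the main value had not, and 10 changed sign, all of these in Arg-TCT values that had not passed. Among these 10, ArgTCT65 in the wild-type arm was −0.0333 under centring on the no-m7G list, −0.0854 under centring on all entries and, with libraries left out, ranged from −0.0369 to 0.15. ArgTCT31 in that arm was −0.0670 and −0.1191 under the centrings and ranged from −0.13 to 0.17. ArgTCT126 in the mutant arm was −0.0020 under centring on all entries and ranged from −0.14 to 0.33. Depth limits the entries below 10 RPM: there were 58, with 7 higher and 1 lower in the wild-type arm. Where a library was left out, the lone sample of that group was assumed to vary like those of the other group. Except where fewer entries, fewer samples or a stricter threshold explain a lower count, the cause was not tested.

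Counts are given as higher and lower entries, and the main ones were 91 and 22 for wild type, 22 and 3 for the mutant, and 34 and 11 for wild type against mutant. Centring on the no-m7G list gave 6 higher for the mutant and 17 higher for wild type against mutant. Centring on all entries, chosen after seeing the data, gave 56 and 42, 13 and 6, and 16 and 17. A minimum of 100 RPM gave 57 higher for wild type. A threshold of 0.01 gave 4 lower for wild type, 13 and 1 for the mutant, and 20 and 6 for wild type against mutant. A minimum change of 1.5-fold gave 35 and 0, 10 and 0, and 16 and 3, and of 2-fold 4 and 0, 2 and 0, and 1 and 0. With 1 value per name without its number the counts were 11 and 4, 1 and 0, and 2 and 1. Of the settings chosen after seeing the data, RPM summed per anticodon gave 12 and 3, 2 and 1, and 2 and 1. Fitting all 3 groups together gave 2 lower for wild type, among 71 calls of which 71 were shared with the 113 of the separate fit, and 5 lower for the mutant. No trend in the prior variance gave 4 lower for wild type and 1 lower for the mutant, and 1 entry per near-identical group gave 8 lower for wild type. The authors' p-values, once adjusted, gave 0 and 0 in both arms, while 87 and 32 of the unadjusted values in the authors' deposited table lay under 0.05 (the limma fits had 135 and 48 there).

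Leaving out each library in turn gave 50 to 116 higher and 0 to 26 lower for wild type, 6 to 25 higher and 0 to 5 lower for the mutant, and 1 to 87 higher and 2 to 43 lower for wild type against mutant. The highest of the last range came without a mutant library, where the spread is taken from the wild-type libraries alone, whose median SD was 0.06 against 0.15 on the log2 scale. The lowest came without a wild-type library. Arg-TCT entries higher with wild type, 1 in the main setting, were 0 at a minimum of 100 RPM, which removes ArgTCT81, 2 with a pseudocount of 10, chosen after seeing the data, and 1 to 2 with a library left out. Those higher with the mutant, 2 in the main setting, were 1 under centring on the no-m7G list, 1 at a minimum of 100 RPM, 1 without the trend and 1 to 3 with a library left out.

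With the replicate number as a block, the mutant arm had 12 higher and 1 lower and wild type against mutant 20 and 5, and the block changed no other count by over 1.5 times. Libraries of the same number did not deviate together (correlations of 0.0927 for empty vector with wild type, −0.116 for empty vector with mutant and −0.0537 for wild type with mutant). These values gave no sign of pairing, but with a single difference per group they cannot exclude it.

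The difference between the m7G and no-m7G families lay near 0 and its sign was not stable. For wild type it was −0.0501 with family medians, −0.0362 with means weighted by RPM, −0.0213 for entries of at least 100 RPM, −0.0292 without Lys and Tyr families, and 0.0913 with the entry as unit, where alone it passed 0.05. For the mutant it was −0.0052 with family medians, −0.0119 with the entry as unit, −0.0504 without Lys and Tyr families and −0.0166 against the Leu, Ser and SeC families. For the difference between the constructs it was 0.0017 with family medians, 0.0445 with the entry as unit and 0.0270 against the Leu, Ser and SeC families. Leaving out each family or, chosen after seeing the data, each library gave −0.0634 to 0.0873 for wild type, −0.0418 to 0.0874 for the mutant and −0.0480 to 0.0066 for the difference. The correlation of the arms was 0.506 by rank, against 0.591, and 0.397 or 0.390 with 1 empty vector library to each arm, chosen after seeing the data. Tests on counts, other count scalings and a list by sequence motif were not run, since the values are RPM and no sequences of the entries were used here.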

Other observations

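By amino acid, the share of reads with wild-type METTL1 lay farthest from empty vector, in percentage points, for alanine. Alanine entries took 31.3 ± 0.388% of tabled reads in empty vector and 28.1 ± 0.153% with wild-type METTL1 (SD, n = 2 libraries each), and 29.5 ± 3.89% with the mutant. Lysine entries took 3.10 ± 0.186%, 3.72 ± 0.0757% and 3.18 ± 0.379% in the same order, and proline entries 1.57 ± 0.102%, 1.99 ± 0.106% and 1.87 ± 0.190%. Aspartate entries took 0.713 ± 0.0255%, 1.10 ± 0.103% and 1.06 ± 0.156%. Glutamate entries took 1.00 ± 0.0044%, 1.35 ± 0.0217% and 1.08 ± 0.116%. Histidine entries took 2.32 ± 0.192% and 2.43 ± 0.0932% but 1.70 ± 0.114% with the mutant. No test was run on these shares. They are shares of the tabled RPM and depend on how near-identical entries are counted. With each near-identical group weighted as 1 entry, chosen after seeing the data, alanine took 24.86 ± 0.0735%, 21.95 ± 0.0593% and 23.52 ± 2.55% in the same order. The means in that order were then 4.392%, 5.200% and 4.511% for lysine, 1.313%, 1.604% and 1.597% for proline and 1.227%, 1.857% and 1.832% for aspartate. They were 1.708%, 2.253% and 1.855% for glutamate and 3.983%, 4.100% and 2.942% for histidine.

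With wild-type METTL1, 5 of 10 glutamate entries rose by limma at a BH-adjusted p under 0.05 and none fell (mean log2 fold change 0.39), and both GlyTCC entries rose (mean 0.45). Of 20 leucine entries 5 fell and 1 rose: all 3 LeuTAG entries fell (mean −0.26, and −0.35 and −0.40 under the 2 centrings), calls that did not hold without wild-type library 1, where 0 entries of any family were lower. None of the 6 tryptophan entries, which are on the m7G list, was called (mean −0.02, range −0.05 to 0.04). TrpCCA1, TrpCCA2, TrpCCA5 and TrpCCA7 among them were near-identical and may not be separate measurements. Of 7 tyrosine entries 1 rose, or 0 under either centring. These families were chosen after their values were seen.

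The tests of explanations below were chosen after the results were seen.

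With wild-type METTL1 scarce entries rose more than abundant ones over all 301 entries (Spearman correlation of log2 fold change with mean RPM −0.488). Entries below 10 RPM cannot be ranked against the others, as the pseudocount of 1 lowers log2 fold changes there. AlaAGC183, at 1.09 RPM in empty vector and 3.26 RPM with wild type, had a log2 fold change of 1.05. The median log2 fold change was 0.26 for 58 entries below 10 RPM, of which 7 passed with a rise, 0.47 for 41 entries at 10 to 100 RPM, 0.29 for 68 at 100 to 1000, 0.06 for 103 at 1000 to 10000 and −0.06 for 31 at 10000 RPM or more. Counting noise is argued against by the Spearman correlation of −0.594 with mean RPM over entries at 10 RPM or more. Its 95% interval from 1000 bootstraps was −0.709 to −0.404, and it was −0.586 to −0.558 with a library left out. As the 2 libraries of a group may be technical, neither range shows whether the relation would recur in other cultures. As a source of this relation, a lift of all other entries by the lower alanine reads is argued against by −0.580 without alanine entries. Such a lift would raise them by the same factor and leave ranks unchanged, so this value cannot decide whether it occurred. Within families, the scarce members exceeded the most abundant one in 23 of 32 families, by a median of 0.21 on the log2 scale. The mutant arm, which was compared with the same empty vector libraries, gave −0.302, and wild type against mutant, which does not use them, −0.378. A difference between lines or libraries other than METTL1 activity may contribute, and this cannot be told apart from the constructs, which coincide with the lines.

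Of the 46 pairs of entries within 1% of each other in all 6 libraries, 20 joined different anticodons of an amino acid and 2 joined different amino acids, GlyCCC14 with AlaCGC2 and ProAGG41 with LeuAAG9. Of the 29 pairs at 10000 RPM or more, 21 lay within 1 group of 7 AlaCGC and AlaTGC entries. There the chi-square per degree of freedom between partners had a median of 0.0093 and was 0.136 at most. Random dealing of reads between partners, simulated with the same 1% selection, gave medians of 0.525 or more in 200 simulations, and is argued against in this group. The value of 0.136 is consistent with the same reads being counted in each of the 7, so calls within this group may count reads several times. Of the other 8 pairs 6 lay above 1, the highest at 9.10, and 2 below 0.5, so there random dealing and repeated counting cannot be told apart.

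The largest fold in the authors' deposited table belonged to AlaGGC139, with 15.4 for wild type and 11.1 for the mutant. It rests on 1 and 0 implied reads in the empty vector libraries, against 4 and 8 with wild type and 4 and 4 with the mutant. Pooled reads scaled to library totals gave a ratio of 10.6 (95% counting interval 1.56 to 451) for wild type and 7.24 (0.970 to 321) for the mutant. In limma, with the pseudocount of 1, its log2 fold change with wild type was 0.52. The entry was chosen after its values were seen.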
